A study of Oryza sativa with 16 samples.

How the data were processed

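The series measured messenger RNA levels in rice leaves (Oryza sativa, cultivar Norin 8) with Agilent microarrays, glass slides on which each spot, or probe, binds 1 transcript sequence and gives a brightness that rises with the amount of that transcript. Plants grew in a growth chamber for 27 days, and the chamber then went from a daily temperature cycle to a continuous temperature. Leaves were taken at 2:00 and 14:00 on day -1, which is before the shift, and on days 2, 4 and 6 after it. The temperatures and the light schedule are not given in the sources used here. Each of the 8 combinations of day and hour has 2 samples, described as biological replicates, which makes 16 samples.

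Per the labels' protocols, total RNA was copied to complementary RNA and labelled with the dyes Cy5 or Cy3. Replicate 1 carries Cy5 and replicate 2 carries Cy3 in every group, and per the labels both replicates of a group were read from the 2 channels of 1 array, a scan that the labels of both samples name. The 8 arrays lie on 2 slides, with day -1 and day 2 on the first slide and days 4 and 6 on the second. Array and group therefore cannot be told apart, and all p-values from the 16 channels measure only the spread between 2 channels of the same array. A comparison of day -1 with days 4 or 6 also crosses slides, whereas 14:00 against 2:00 within a day, and day 2 against day -1, do not. On both slides the arrays of 2:00 and 14:00 alternate in position, and day -1 and day 2 take different positions. An effect of position was therefore not told apart in these comparisons.

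The deposited table holds 1 intensity per probe and sample on a linear scale, and the submitters' processing notes name Agilent Feature Extraction as the software. Its version, the background correction and the normalization are not given in the sources used here. In these deposited intensities the 2 channels of an array had medians within a factor of 1.02 of each other, while medians differed up to 2.67-fold between arrays, so the channels of an array were on a common scale and the arrays were not. The table has 45082 rows, named by feature number only. The files do not pair feature numbers with genes, so probes are reported by number, the gene lists fixed in advance could not be tested, and no genome position is given. The table has no flags for control spots, spots below background or saturated spots, and all rows were tested as separate probes.

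The intensities were put on the log2 scale and, since the medians of the columns differed by more than 0.1, quantile normalized over the 16 columns (limma 3.58.1 in R 4.3.3). This gives each sample the same distribution of values, with a median of 8.11, a 25th percentile of 4.09 and a 10th percentile of 1.66 log2 units. Levels near 1.66 are described as the floor of the table. A difference from such a level depends on a background correction that is not known here, and its size is uncertain. A single limma model with 8 group means was fitted to all 16 samples, with empirical Bayes moderation and an intensity trend, and the contrasts were adjusted by the Benjamini-Hochberg method over all probes. A probe was called, and is described as higher or lower, when the adjusted p was under 0.05 and the log2 difference was at least 1 in size, which is 2-fold. Every adjusted p below is from this limma fit unless another setting is named. Errors of log2 differences are the fit's standard errors (SE), and levels are given as mean ± SD in normalized log2 units.

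The comparisons were 14:00 minus 2:00 on each day and over days 2, 4 and 6 together, the change of that difference after the shift (the mean of days 2, 4 and 6 minus day -1), and the mean of days 2, 4 and 6 minus day -1 at each hour, with day 2 minus day -1 alone as the comparison within 1 slide. The rule for named probes was the largest differences in each direction among called probes whose samples did not overlap between the sides, or, for the change of the difference, whose replicates moved the same way. The rule was set at 8 per direction, and 2 per direction are printed because the probes have no gene names. Groups, comparisons, thresholds, the rule for named probes and most alternatives were set before the data were examined. Tests with another day in the place of day -1 (with and without day 6), with 50 added to the intensity, within 1 dye, and without both samples of day 6 at 2:00 were added after seeing the data.

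The replicate number marks the dye, and a fit with it as a block was an alternative. The fit was tested on simulated data with the real probes' levels, dye differences and spread over all 45082 probes. Of 50 probes given a 4-fold difference the fit called 46% for 14:00 against 2:00 on day -1, 62% for the same over days 2, 4 and 6, 40% for the change of the difference, and 56% for after against before at either hour. For a 2-fold difference these shares were 10%, 22%, 10%, and 20% at 2:00 and 16% at 14:00. The simulation had no array effects. The number of arrays limits the precision.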

Results

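Leaf RNA of rice cultivar Norin 8 was compared between 2 hours of the day and between leaves taken under a daily temperature cycle and leaves taken after a shift to continuous temperature. The data consist of 45082 probes in 16 samples, 2 for each of 8 combinations of day and hour. Median deposited intensities ran from 219 to 278 on 7 of the 8 arrays, whereas the array of day 6 at 2:00 had medians of 585 in Cy5 and 572 in Cy3. Between 16.6% and 24.2% of the probes of a sample had an intensity below 10. After normalization the replicates of a group correlated across probes at r = 0.93 to 0.99, and samples of different hours at r = 0.91 to 0.96. The lowest replicate correlation was that of day 6 at 2:00, where 34.4% of the probes were 2-fold or more apart between the replicates, against 8.59% to 14.6% in the other 7 groups.

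The first principal component of the samples, computed on the 31558 brighter probes with the mean of each dye removed, held 56.3% of the variance and separated the 8 samples of 2:00 from the 8 of 14:00. The second held 22.2%. At 2:00 it placed both day -1 samples at -55.0 and -126, the day 2 and day 4 samples between 6.27 and 44.4, and the day 6 samples at -119 in Cy5 and 95.4 in Cy3. At 14:00 the replicates of day -1 stood at 21.6 and -77.2 and those of day 6 at 63.5 and -57.0, so this component did not separate before from after at that hour.

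**Figure D1:**
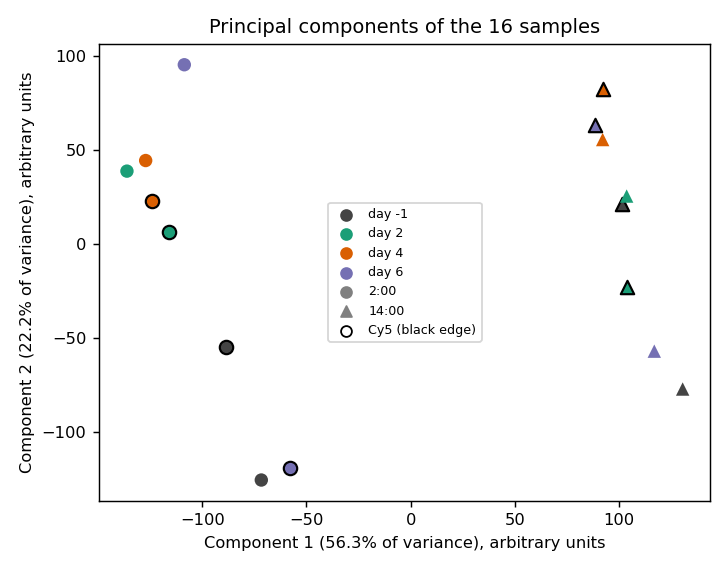
Each point is 1 of the 16 samples, placed by its first (horizontal, 56.3% of variance) and second (vertical, 22.2%) principal component in arbitrary units, with the day as colour, 2:00 as circles, 14:00 as triangles and Cy5 as a black edge. The hours lie on opposite sides of 0 on the horizontal axis, and the 2 samples of day 6 at 2:00 lie at -119 and 95.4 on the vertical axis.

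The first question was which transcripts differed between the hours under the daily temperature cycle. On day -1, 6854 probes (15.2% of those tested) differed between the hours. Of these, 3426 were higher at 14:00 and 3428 were higher at 2:00. At least 4-fold differences were found in 1519 probes higher at 14:00 and 1083 higher at 2:00. The figures for 16-fold were 380 and 151. Probe 30391 stood at 15.16 ± 0.32 log2 units at 14:00 and 2.94 ± 0.53 at 2:00 (SD, n = 2 each), a difference of 12.22 (SE 0.79, limma adjusted p = 7.35e-06). Its 2:00 level was dim, and with 50 added to the intensities the difference was 9.29. Probe 41277 followed with a difference of 11.75 (SE 0.51, limma adjusted p = 6.04e-07). In the other direction probe 41308 stood at 2.51 ± 0.96 at 14:00 and 13.49 ± 0.16 at 2:00, a difference of -10.98 (SE 0.38, limma adjusted p = 1.49e-07), or -7.67 with 50 added. Probe 13388 differed by -9.73 (SE 0.59, limma adjusted p = 5.1e-06), and by -5.998 with 50 added to the intensities. The dimmest 25% of the probes held 541 of the called ones. The even split of directions depended on the scaling. It was 3017 higher at 14:00 and 4112 higher at 2:00 without normalization between arrays. With each column centred on its median it was 3656 and 3210. With arrays instead of channels as replicates, and days 2, 4 and 6 supplying the spread, 5427 probes were called. In the same way within 1 dye, 1958 were called in Cy5 and 3509 in Cy3.

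The next comparison asked which hour differences were present under continuous temperature. The mean of days 2, 4 and 6 differed between the hours in 9161 probes, 4423 higher at 14:00 and 4738 higher at 2:00. With arrays as replicates 8250 were called. Probe 38895 stood at 16.63 ± 0.32 at 14:00 and 5.47 ± 0.75 at 2:00 (SD, n = 6 each), a difference of 11.16 (SE 0.25, limma adjusted p = 1.9e-09). Probe 30391 differed by 10.76 (SE 0.46, limma adjusted p = 1.2e-07), and by 8.59 with 50 added to the intensities. Probe 41308 was lower at 14:00, with a difference of -11.47 (SE 0.22, limma adjusted p = 1.13e-09). Its 14:00 level of 1.67 ± 0.11 was at the floor of the table, and with 50 added to the intensities the difference was -7.41. Probe 18018 differed by -8.79 (SE 0.32, limma adjusted p = 4.62e-08). Without normalization between arrays the split was 2843 higher at 14:00 and 9343 higher at 2:00. The median of all probes then shifted by -0.50.

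By single days, 8233 probes were called on day 2 (3680 higher at 14:00, 4553 higher at 2:00), 7819 on day 4 (3534 and 4285) and 5556 on day 6 (2898 and 2658). Of the 6854 probes called on day -1, 4731 were called in the same direction on day 2, 4516 on day 4 and 4008 on day 6. Independent lists would share 626, 594 and 422 in the same direction. Calls in opposite directions numbered 22, 20 and 33. Across probes the hour differences of day -1 correlated with those of day 2 at r = 0.69, of day 4 at r = 0.70 and of day 6 at r = 0.76, and those of days 2 and 4 at r = 0.83. Those of day 6 correlated with those of day 2 at r = 0.68 and of day 4 at r = 0.66, below the values for day -1. Day 6 includes the 2:00 group whose replicates lay furthest apart. Probes are not independent replicates. A set of 3145 probes was called in 1 direction on all 4 days, 1534 of them higher at 14:00 and 1611 higher at 2:00. Without the Cy5 sample of day 6 at 2:00 the day 6 count was 9856 (4529 higher at 14:00, 5327 higher at 2:00), and without the Cy3 sample it was 7002 (3405 and 3597), which turned the balance of directions. Without normalization between arrays it was 19523 (1019 higher at 14:00, 18504 higher at 2:00). Without the Cy3 sample of day 2 at 2:00 the day 2 count was 5040, and without the Cy5 sample of day 4 at 14:00 the day 4 count was 5112.

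**Figure D2:**
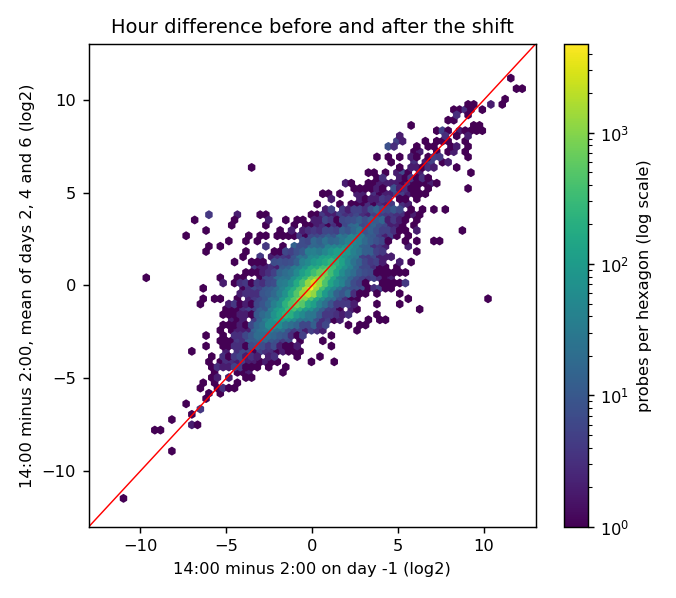
Each hexagon counts probes (colour, log scale) by their 14:00 minus 2:00 difference on day -1 (horizontal, log2) and the mean of the same difference over days 2, 4 and 6 (vertical, log2), with the line of equal differences in red. The hour differences correlate across probes, and single probes lie far from the line, such as probe 13388 at -9.73 before and 0.27 after.

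The size of the hour difference was compared between days in the 8233 probes called on day 2, so that the day used for choosing did not enter the comparison. Signed by their direction on day 2, these probes had a median difference of 1.31 log2 units on day -1 (1.26 in replicate 1 and 1.36 in replicate 2), 1.49 on day 4 (1.53 and 1.47) and 1.16 on day 6 (0.98 and 1.36). The same direction as on day 2 was seen in 95.3% of the probes on day -1, 97.8% on day 4 and 93.9% on day 6. With 2 replicates a day no test of these medians was made. Day 2 is itself a day of continuous temperature, so the choice leaves out probes that differed on day -1 alone. It can therefore favour day 4 over day -1 without a change in size. On day 6 replicate 1 holds the Cy5 sample of 2:00, which lay far from its replicate. Probes higher at 14:00 had medians of 1.51 on day -1, 1.67 on day 4 and 1.35 on day 6, and probes higher at 2:00 had 1.19, 1.39 and 1.07. In the deposited values without normalization between arrays the medians were 1.29 on day -1, 1.53 on day 4 and 1.77 on day 6. The median of all probes was then shifted by -1.02 on day 6, and the 1.77 was made up of 0.33 in probes higher at 14:00 and 2.07 in probes higher at 2:00.

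The change of the hour difference after the shift was tested as an interaction. It was called for 223 probes, 80 in which 14:00 gained on 2:00 and 143 in which 2:00 gained on 14:00. In 57 of these the difference kept its sign and was smaller after the shift, and in 22 it was larger. In 144 the sign of the fitted difference changed, with 13 probes called in opposite directions before and after. The change was larger at 2:00 in 121 probes and at 14:00 in 102. Probe 13388 had 11.74 ± 1.45 log2 units at 2:00 on day -1 (SD, n = 2) and between 1.48 and 2.17 in every other group, a change of 10.00 (SE 0.69, limma adjusted p = 9.65e-05). Probe 40716 changed by 9.07 (SE 1.47, limma adjusted p = 0.0299), from -6.16 on day -1 to -1.05, 3.43 and 6.32 on days 2, 4 and 6. Its call ended under 13 of 29 alternatives, among them arrays as replicates (limma adjusted p = 0.639; range over the alternatives 0.0124 to 1). Probe 21389 was at 13.17 ± 2.28 at 14:00 on day -1 and between 2.83 and 3.79 in every other group, a change of -10.77 (SE 1.26, limma adjusted p = 0.00356). Probe 11551 changed by -7.68 (SE 0.89, limma adjusted p = 0.00353), from 6.27 to -1.40. Within Cy5 alone the calls of probe 13388 (limma adjusted p = 0.0853; range over the alternatives 1.51e-05 to 0.0853) and of probe 11551 (0.198; range 0.000119 to 0.198) ended. With 50 added to the intensities the changes were 6.02 for probe 13388, 4.605 for probe 40716, -7.42 for probe 21389 and -4.99 for probe 11551.

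Of the 223 probes, 147 were in the dimmest 25%. When the dimmest 30% of probes were left out of the fit, 16 were called. Setting each later day apart from the other 3 in the same way gave 164 probes for day 2, 177 for day 4 and 240 for day 6. In the fit over all probes, the brighter 70% held 67 calls for day -1, the highest count, against 12, 16 and 38. The 16 called with the dimmest 30% left out came from a separate fit, which is not given for the later days. With 50 added day -1 also had the highest count, 104 against 60, 53 and 88. With day 6 left out of the fit day -1 gave 554, day 2 gave 165 and day 4 gave 194. With arrays as replicates 59 probes were called, 33 in which 14:00 gained and 26 in which 2:00 gained. Within Cy5 alone 48 were called and within Cy3 alone 182 (100 and 82). With each column centred on its median the count was 58 (10 and 48), and without normalization it was 333 (30 and 303). Without the Cy5 sample of day 6 at 2:00 it was 492 (228 and 264), and without the Cy3 sample of day -1 at 2:00 it was 121 (51 and 70). The balance of directions turned without the Cy5 sample of day -1 at 2:00, to 160 in which 14:00 gained and 115 in which 2:00 gained, and with arrays as replicates and within Cy3 alone. Of the 1252 probes called for an hour difference on day -1 and on no later day, 86 were called for the change itself. Of the 434 called in 1 direction on days 2, 4 and 6 but not on day -1, 8 were called for it.

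**Figure D3:**
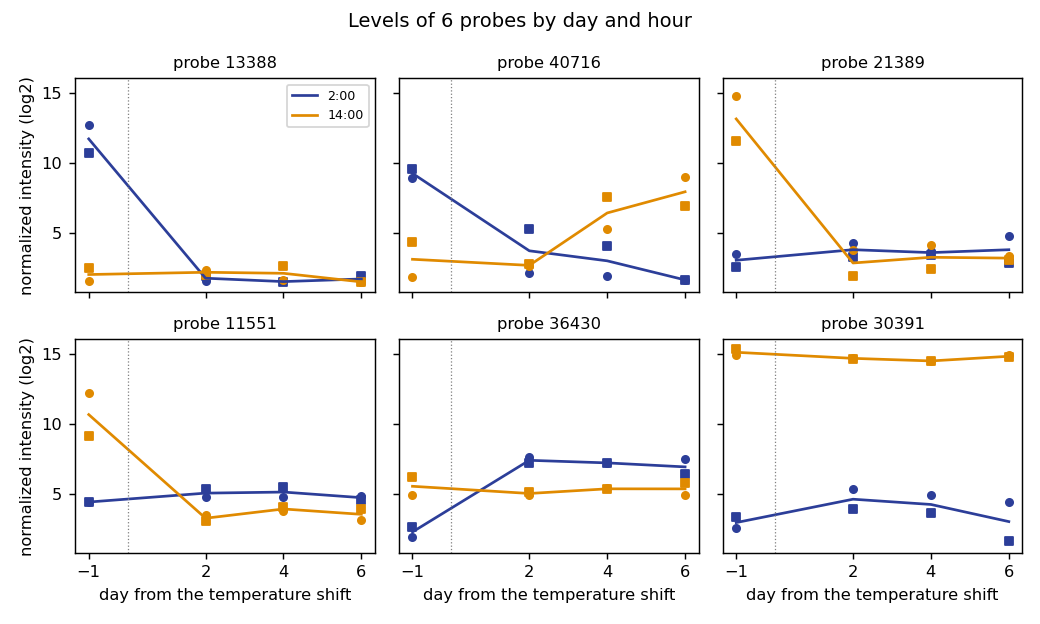
Normalized intensity (vertical, log2) of 6 probes by day from the shift (horizontal, dotted line at the shift) at 2:00 (blue) and 14:00 (orange), with replicate 1 (Cy5) as squares, replicate 2 (Cy3) as circles and lines through their means. Probes 13388, 21389 and 11551 are high on 1 array of day -1, and the 14:00 mean of probe 30391 lies between 14.53 and 15.16 on all days.

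At 2:00, 331 probes differed between the mean of days 2, 4 and 6 and day -1, 151 higher and 180 lower after the shift. Probe 36430 was higher after the shift, 7.19 ± 0.43 (SD, n = 6) against 2.26 ± 0.53 (n = 2), a difference of 4.92 (SE 0.42, limma adjusted p = 0.000407). Within Cy5 alone it was not called (limma adjusted p = 0.161; range over the alternatives 0.00011 to 0.161). Probe 16576 was higher by 4.20 (SE 0.39, limma adjusted p = 0.000741), from a day -1 level of 1.40 ± 0.01 at the floor of the table. With 50 added to the intensities the difference was 1.85 for probe 36430, -6.03 for probe 13388 and -5.20 for probe 42373, and that of probe 16576 was 0.95 and was not called (limma adjusted p = 0.0602; range over the alternatives 8.86e-05 to 0.0602). Probe 13388 was lower, with a difference of -10.09 (SE 0.49, limma adjusted p = 6.91e-06). Probe 42373 had a difference of -7.21 (SE 1.35, limma adjusted p = 0.0432). Its call ended under 16 of 31 alternatives, among them arrays as replicates (limma adjusted p = 0.165; range over the alternatives 0.00472 to 1). The median change of the probes higher after the shift was 1.64 on day 2, 1.34 on day 4 and 1.52 on day 6. That of the lower ones was -1.53, -1.95 and -1.93. These probes were chosen on the mean of the same days against the same day -1 array, which favours a shared sign on each day. Within the first slide, day 2 minus day -1 was called for 213 probes, 136 higher and 77 lower on day 2, a balance that turned when single samples were left out.

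The counts at 2:00 depended on single samples, and so did the balance of directions. All groups share the fit's estimate of the spread. Among the brighter probes the replicate difference of day 6 at 2:00 had an SD of 1.51 log2 units, against 0.39 to 0.94 in the other groups. Leaving out a sample of that group takes this gap out of the spread, also for comparisons without day 6, such as day 2 minus day -1. Without the Cy5 sample of day 4 at 2:00 there were 175 higher and 168 lower, and with the dimmest 30% of probes left out 56 higher and 47 lower. Without the Cy5 sample of day 6 at 2:00 the 331 became 4571 (1871 higher, 2700 lower), and without both samples of that group 2398 (963 higher, 1435 lower). Without the Cy3 sample of day -1 at 2:00 it was 95. Leaving out the Cy3 sample of day 2 or of day 4 at 2:00 gave 209 and 191. Leaving out the Cy5 or the Cy3 sample of day 2 at 14:00 or the Cy3 sample of day 4 at 14:00 gave 216, 206 and 220. With arrays as replicates 134 were called (30 higher, 104 lower), with slide as a block 109, within Cy5 alone 39 and within Cy3 alone 1153. Setting day 6 apart gave more probes, 670, than setting day -1 apart, and days 2 and 4 gave fewer, 226 and 197. Of these calls the brighter 70% held 356 for day 6, 154 for day -1, 53 for day 2 and 19 for day 4. With 50 added the counts were 264 for day 6, 158 for day -1, 130 for day 2 and 30 for day 4. With day 6 left out of the fit day -1 gave 2707, day 2 gave 171 and day 4 gave 375. Without normalization between arrays the split was 3647 higher and 402 lower. The 213 probes of day 2 against day -1 became 106 without the Cy3 sample and 337 (137 higher, 200 lower) without the Cy5 sample of day -1 at 2:00, and 130 without the Cy3 sample of day 2 at 2:00. It became 996 (403 higher, 593 lower) and 984 (397 and 587) without the Cy5 or Cy3 sample of day 6 at 2:00, 37 with the dimmest 30% left out, and 765 (620 higher, 145 lower) without normalization.

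At 14:00, 293 probes differed between the mean of days 2, 4 and 6 and day -1, 86 higher and 207 lower after the shift. Probe 21389 was lower, 3.09 ± 0.82 (SD, n = 6) against 13.17 ± 2.28 (n = 2), a difference of -10.08 (SE 0.89, limma adjusted p = 0.000558). Probe 11551 was lower, with a difference of -7.12 (SE 0.63, limma adjusted p = 0.000559). It was not called within Cy5 alone (limma adjusted p = 0.0787; range over the alternatives 4.29e-05 to 0.0787). Probe 43184 had a difference of 5.47 (SE 1.05, limma adjusted p = 0.0477). Its call ended under 22 of 30 alternatives, among them the replicate block (limma adjusted p = 0.0509; range over the alternatives 0.0298 to 1). With 50 added to the intensities its difference was 2.26, that of probe 21389 was -7.28 and that of probe 11551 was -4.79. Probe 42747 had 4.20 (SE 0.74, limma adjusted p = 0.0341), a call that ended under 17 of 30 alternatives (range over the alternatives 0.0142 to 1). The median change of the lower probes was -1.29 on day 2, -1.99 on day 4 and -1.85 on day 6, and that of the higher ones was 1.06, 1.65 and 1.51. As at 2:00, the choice of these probes favours a shared sign on each day. Day 2 minus day -1 was called for 98 probes, 42 higher and 56 lower. Without normalization between arrays there were 23 higher and 15 lower. With the dimmest 30% of probes left out, 0 were called by limma, and 2171 of the 31558 probes had an unadjusted p under 0.05. A share of 0.05 of the probes would do so without any difference.

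With arrays as replicates 34 probes were called at 14:00, all 34 lower after the shift. The slide block gave 75 (7 higher, 68 lower), Cy5 alone 49 (all 49 lower), and Cy3 alone 134 (6 and 128). Values without normalization between arrays gave 189 (107 and 82), which turned the balance of directions. Setting a later day apart gave 97 probes for day 2, 173 for day 4 and 168 for day 6, all below the 293 of day -1. Of these calls the brighter 70% of probes held 122 for day -1 and 3, 39 and 31 for the later days. With day 6 left out of the fit day 4 gave the highest count, 639, against 453 for day -1 and 88 for day 2. Leaving out the Cy3 or the Cy5 sample of day -1 at 14:00 gave 119 and 174, leaving out the Cy3 sample of day 2 at 14:00 gave 159 (and 63 in place of 98 for day 2 alone). Leaving out the Cy5 or Cy3 sample of day 6 at 2:00 gave 581 and 583. Of the probes called at either hour, 34 were called at both. Of these 31 were lower and 1 higher after the shift at both hours, and 2 went in opposite directions. Independent lists would share 0.83 lower and 0.29 higher. The lists are not independent by design, since at both hours days 4 and 6 lie on another slide than day -1.

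**Figure D4:**
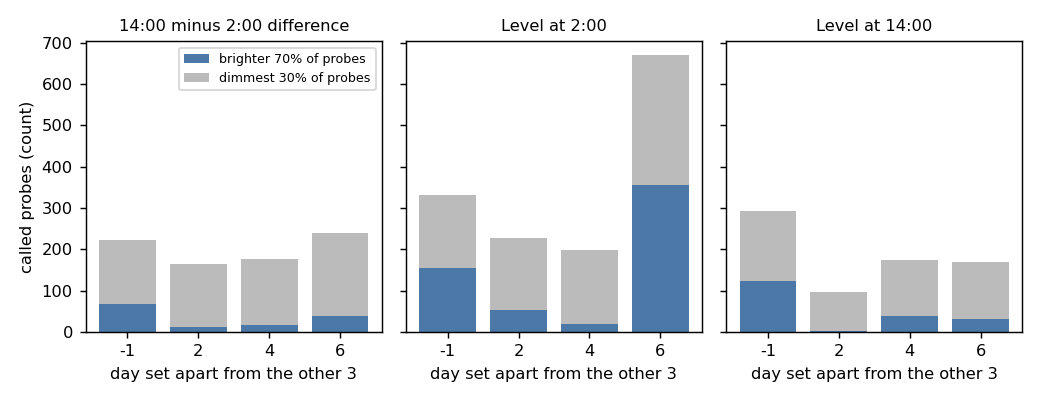
Bars count the probes called when the day on the horizontal axis is compared with the mean of the other 3 days, for the 14:00 minus 2:00 difference, the level at 2:00 and the level at 14:00 (blue, the brighter 70% of probes; grey, the dimmest 30%). Day 6 has the highest count at 2:00 (670) and day -1 at 14:00 (293).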

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

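The comparisons with another day in the place of day -1, with and without day 6, were chosen after the counts for day -1 were seen, while the slide and single-spot tests were written before their results. The test of the change itself set 223 probes apart as differing in their hour difference between the daily temperature cycle and continuous temperature, and 6 of the named probes are among them. Their changes of the 14:00 minus 2:00 difference in log2 units were 10.00 for probe 13388, 9.07 for probe 40716, -10.77 for probe 21389, -7.68 for probe 11551, -5.22 for probe 36430 and -3.93 for probe 16576.

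Array differences unrelated to the shift may account for a part of the differences between day -1 and the later days and stay open: with day 6 set apart the same contrast called 240 probes for the hour difference and 670 for the level at 2:00, above the 223 and 331 of day -1, and at 14:00 the highest other count was 173 against 293. Day 6 decided this. With it left out, day -1 gave 554 against at most 194 for the hour difference (317 against 20 among the brighter 70% of probes). At 2:00 day -1 then gave 2707 against at most 375 (2010 against 147), whereas at 14:00 day 4 gave 639 against 453. With a later day set apart, day -1 stays among the days it is compared with. A change that went on after the shift would enter too. These counts therefore do not measure array differences alone. A slide difference stays open at both hours. At each hour 200 probes were chosen on days 4 and 6 in Cy5. Their change in Cy3 on day 2, which shares the slide of day -1, was divided by that on days 4 and 6. The ratio was 0.965 at 14:00 (95% bootstrap interval over probes 0.67 to 1.61) and 0.405 at 2:00 (0.09 to 0.77). Probes are not independent replicates, and the intervals hold no spread between arrays. The day -1 array enters the choice and both changes, so a ratio up to 1 can arise without the shift. The bound set beforehand was therefore too low. With slide as a block the 293 probes at 14:00 became 75 and the 331 at 2:00 became 109. Single spots that were bright or dark on 1 array, which both replicates share, stay open for a part: 21.1% of the 223 probes had 1 day -1 array 2 log2 units or more from all 7 others, and such probes numbered 106 and 53 on the day -1 arrays and 24 to 173 on the other 6. Of the named probes flagged above, 13388, 21389, 11551, 36430 and 16576 had 1 day -1 array apart in this way, and only 40716 did not. A single spot therefore stays open for most of the flagged named probes. The end of the daily temperature cycle, and plant age, remain as untested explanations for the rest of the differences between day -1 and the later days.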

How the results depend on the processing

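The fits with 50 added to the intensity, within 1 dye and without both samples of day 6 at 2:00 were chosen after seeing the data. Each group has 1 array, and signal over background is not known, which limits every comparison. Of 262 counts recomputed under the alternatives, 200 stayed within 1.5 times the count reported. These pool the hour differences with the comparisons of before and after, which were less stable. With the dimmest 30% of probes left out, for example, every hour-difference count stayed and every count for the shift moved. For the single probes named, the other alternatives kept the call in 232 cases and lost it in 30, leaving out 1 sample kept it in 277 and lost it in 43, and the direction reversed in 0. The named probes were chosen without overlap between the sides, or with replicates that moved the same way. That rule left little room for a reversal when 1 sample was left out. The sample that stays in the group is the other channel of the same array, so such fits do not test an effect of the array. The probes that lost calls when a sample was left out were 40716, 42373, 42747 and 43184, and where this left 1 sample in a group, that sample was assumed to vary like the other groups. Within Cy5 alone probes 13388, 11551 and 36430, and with 50 added probe 16576, also lost a call. The fits with 50 added made every named log2 difference smaller. For probes 13388, 40716, 36430, 16576 and 43184 this was by over 1.5 times on the log2 scale. For probe 41308 that held over days 2, 4 and 6 but not on day -1. For probe 11551 it held for the change of the difference but not at 14:00. Probe 30391 went from 12.22 to 9.29 and from 10.76 to 8.59, and probe 21389 from -10.77 to -7.42 and from -10.08 to -7.28. Averaging the probes of a gene and testing gene lists were not run, because probes have no gene names. The cause was not tested for the moves below except where the setting tests fewer probes or samples. Leaving out a sample of day 6 at 2:00 also changes the spread that all groups share in the fit.

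Samples with the same replicate number, which marks the dye, did not all deviate from their group means together: over 28 pairs of groups the correlation ran from -0.48 to 0.60 (median 0.07), with 12 over 0.1. With the replicate block the counts were 6878 for day -1, 9149 for days 2, 4 and 6, 225 for the change of the difference, 348 for after against before at 2:00 and 314 at 14:00, and the call of probe 43184 was the only one among the named probes that it ended. Within 1 dye, with days as replicates, day -1 had 1958 probes in Cy5 and 3509 in Cy3, the change of the difference 48 and 182, after against before 39 and 1153 at 2:00 and 49 and 134 at 14:00. With adjusted p alone, days 2, 4 and 6 had 19349 probes and day 6 had 8347, and the medians of probes chosen on day 2 were 0.99 on day -1, 1.16 on day 4 and 0.88 on day 6.

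Without normalization between arrays the counts were 4049 for after against before at 2:00, 189 at 14:00, 19523 for day 6, 765 for day 2 against day -1 at 2:00 and 38 at 14:00, and the day 6 median of probes chosen on day 2 was 1.77; the median of all probes shifted by -1.02 for the day 6 hour difference. Centring each column on its median gave 58 for the change of the difference, and 140 and 34 for day 2 against day -1 at 2:00 and 14:00; after against before at 14:00 was then 26 higher and 173 lower. With the dimmest 30% of probes left out the change of the difference had 16, after against before 103 and 106, and day 2 against day -1 37 and 0. With 50 added to the intensity these 5 counts were 104, 158, 117, 141 and 33.

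With arrays as replicates the change of the difference had 59 probes and after against before 134 and 34, and with slide as a block the latter had 109 and 75. Without day 4 after against before had 162 (93 higher, 69 lower) and 120 (52 and 68). Without day 6 the change of the difference had 554 and after against before 2707 and 453, and without both samples of day 6 at 2:00 the change had 540 and after against before at 2:00 had 2398. Leaving out each sample in turn gave ranges of 121 to 492 for the change of the difference, 95 to 4571 and 119 to 583 for after against before at 2:00 and 14:00, 5040 to 9837 for the hour difference of day 2, 5112 to 9470 for day 4, 4144 to 9856 for day 6, and 106 to 996 and 63 to 119 for day 2 against day -1 at 2:00 and 14:00.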

Other observations

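The correlations in this paragraph were chosen after seeing the data. The change of level between a day and the other 3 days was shared between the hours for some days. Over the 31558 brighter probes, the difference of the other days from day -1 at 2:00 correlated with that at 14:00 at r = 0.44, and for day 4 set apart the value was 0.41, against -0.08 for day 2 and 0.09 for day 6. The 2 hours share no array, but both hours of a day lie on the same slide. A slide difference can therefore enter both hours alike. Since 1 of the other 3 days always shares the slide of the day set apart, it enters with the same weight for every day. The values of -0.08 and 0.09 for days 2 and 6 argue against a slide difference alone as the source of 0.44 and 0.41. Whether it adds to each value was not told apart here. Probes are not independent replicates.

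The tests of dye bias and of a mislabelled sample in this paragraph were chosen after the sample correlations were seen, the test of brightness before its result. The 2 replicates of day 6 at 2:00 lay far apart: on an axis from day -1 (0) to the mean of days 2 and 4 (1) at 2:00, with its direction taken from the other dye, the Cy3 sample stood at 0.86 and the Cy5 sample at -0.60. A dye bias common to all arrays is argued against, since with the mean dye difference of the other arrays removed the SD of the replicate difference was 1.51 log2 units, against 0.39 to 0.94 in the other 7 groups. An effect of that array's higher brightness stays open: the SD was 1.51 after loess within each array too, but loess moved the SD of no group by more than 2.18% and so tested little. A mislabelled Cy5 sample may explain the position of -0.60, which is on the side of day -1, although it lies beyond the day -1 sample. A difference between the plants sampled remains open and was not tested.

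The division of the 6 arrays after the shift by hour called 8895 probes with day and dye in the fit. With both channels of an array kept together there are 10 divisions into 3 and 3, of which 1, the one by hour, gave as many, and the highest of the others gave 160. These divisions, counted in this way after the result was seen, are too few for a share under 0.05. Each of the others also puts arrays of both hours on the same side. The hour difference then enters their spread, so the 160 is not a level to set the 8895 against.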
